A study of Etheostoma caeruleum with 18 samples.

How the data were processed

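Liver RNA of wild-caught rainbow darter (Etheostoma caeruleum), a small North American river fish, was profiled by sequencing in 18 fish, 1 library each. The labels place 6 fish in each of 3 groups, namely unexposed controls, fish held in water with 1 µg/L of R-venlafaxine, and fish held with 1 µg/L of S-venlafaxine, all for 14 days. Venlafaxine is an antidepressant that inhibits the reuptake of serotonin and noradrenaline, and its R and S forms are mirror images of each other. Per the labels' protocols, polyA RNA was made into libraries with a strand-preserving kit, NEBNext Ultra II Directional. Per the labels' protocols, tanks, each holding several fish, were assigned to the groups at random. The labels do not say which fish shared a tank, so every p-value rests on the spread between fish and a difference between tanks cannot be separated from it. The tests treat fish as independent. If fish of 1 tank resemble each other, a tank difference also enters the difference between groups and the p-values can be too small.

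Per the submitters' processing notes, the tools were Trimmomatic 0.36, Bowtie2 2.2.7 and RSEM 1.3.1. The identifiers in the deposited tables follow the naming pattern of a Trinity assembly, so each "gene" is an assembled unit. The settings of each tool are not given in the sources used here. The deposited count table holds estimated counts for 302933 assembled genes in 253445 components, where a component groups the genes that share the first part of the identifier. The deposited TPM table lists relative transcript abundance within each library for the same genes, rounded by the authors to 0.01, and each library sums to between 999995 and 1000004.6.

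The relation of the 2 tables was checked on their values. Each deposited estimated count, expressed per unit of its library's total and scaled as TPM is, equalled the deposited TPM, within 0.0055, for 99.977% of values. Of 745618 values above 0 and below 10 estimated counts, 0.489% were whole numbers and all, 100.0%, were whole steps of 0.01 TPM. The deposited counts are therefore TPM values rescaled to each library's total, they carry no weight for gene length, and a count from them is not a number of reads. The variance that a count model assigns to low genes is then approximate, and results from the 2 tables are not independent of each other. For this reason values are given in TPM, and no fold change is given where a whole group is listed at 0.

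Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), which kept 59733 genes, 19.7% of those listed, holding 97.4% to 98.9% of each library's total. Library sizes were scaled by TMM. The main test was edgeR's quasi-likelihood test with robust estimation (edgeR 4.0.16 in R 4.3.3), fitted once to all 18 libraries with group means only, followed by 3 contrasts between pairs of groups and a joint test of all 3 groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and tests between 2 groups were two-sided. Permutation tests of the variance between groups, and counts over random splits, counted only results at least as large as the real one. Interval statements use 95% confidence intervals of the log2 fold change. Distances between libraries were computed on log2 CPM with a prior count of 2 and tested for group differences with the distance-based method of vegan 2.7.1 and 9999 permutations. Measures with 1 value per library were compared by exact permutation of 6 against 6 libraries. Benjamini-Hochberg adjustment was made over the 18 tests of depth and composition and over the 12 tests of gene blocks. The tests of the spread between fish were not adjusted. The remaining steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

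The test was tried on simulated data. Counts were drawn for all 59733 genes from the real means and library sizes with 200 genes changed, and, separately, known changes were implanted into 200 real genes with 3 draws for each fold size. The changed genes were drawn in both cases from those with a mean log2 CPM of at least 0. In the simulated data the test made 138, 142 and 143 calls for R-venlafaxine against control, S-venlafaxine against control and S-venlafaxine against R-venlafaxine, of which 0, 3 and 2 were genes left unchanged. Of the unchanged genes, 6.09%, 5.96% and 5.93% had an unadjusted p under 0.05, above the rate of evenly spread p-values. The real libraries gave counts below that rate, so the simulation does not reproduce their p-values.

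The groups, the tests of the comparisons, the rule for naming genes and the alternatives were fixed before the data were examined, except 4 alternatives and the tests that the closing section names as chosen later. The deposited tables do not pair the identifiers with gene names. The rule for that case names at most 2 identifiers that were higher and 2 that were lower, taking for each exposure against control the gene with the lowest p in each direction among genes with a mean log2 CPM of at least 0. One further gene outside the rule is named because it was the only gene called by edgeR's main test, and it was chosen after its values were seen. The 21 gene lists fixed in advance, on drug metabolism, monoamine signalling, stress, lipid, immune and other functions, and the 9 lists of cell type markers were not run, since none of their symbols could be matched. Alternatives covered the scaling, the low-count filter, the estimation of the spread, the samples in the fit, blocks by replicate number or library letter, DESeq2 1.42.0, limma 3.58.1 (voom, and log2 TPM with pseudocounts of 0.5 and 1) and leaving out each library. No column of per-sample values was left out.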

Results

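Liver transcriptomes of 18 rainbow darters were compared after 14 days in clean water or in water with 1 µg/L of one mirror-image form of the antidepressant venlafaxine, with 6 fish per group. Library totals ranged from 43.8 to 65.6 M estimated counts (M, mega) and averaged 54.7 ± 9.23 M in controls, 55.9 ± 4.39 M in R-venlafaxine fish and 50.0 ± 1.75 M in S-venlafaxine fish (SD, n = 6 each). Of 302933 assembled genes, 288593 were above 0 in at least 1 library and 40096 in all 18. Between 27111 and 34500 genes per library reached 1 TPM, and 17243 genes did so in every library. Expression was concentrated, as the 10 most abundant genes held 14.9% to 18.4% of a library and the 100 most abundant held 42.6% to 49.1%. The deposited tables do not pair assembled genes with names, so genes are given by identifier and no function is attached to them.

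The first question was whether the liver transcriptome as a whole differed by exposure. No separation by group was detected. Group membership accounted for 12.03% of the variance of log2 CPM over 59733 genes, against 11.76% with no difference between groups (distance-based permutation test, permutation p = 0.2048). The first principal component held 8.39% and the second 7.0% of the variance. Neither passed a test of differences between groups (permutation adjusted p = 0.635 and 0.481). The letter A, B or C in the library names, whose meaning the labels do not state, accounted for 11.81% (permutation p = 0.3957).

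**Figure D1:**
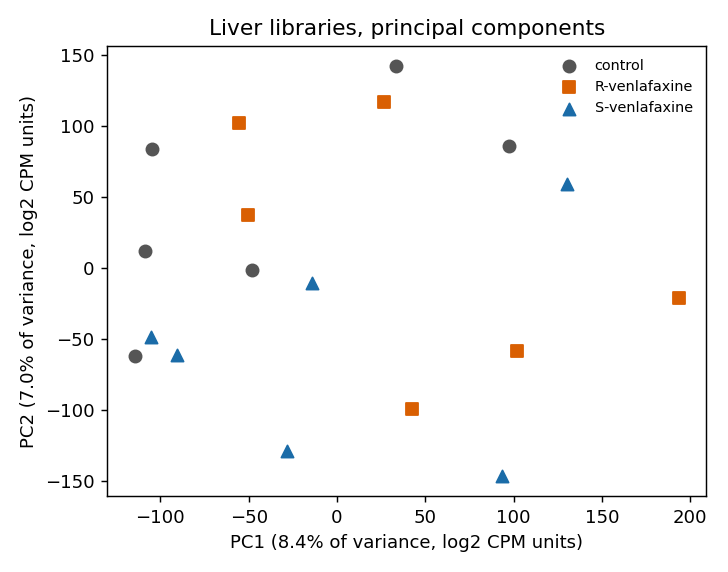
Scores of the 18 liver libraries on the first principal component (horizontal, 8.39% of the variance) and the second (vertical, 7.0%), computed on log2 CPM, with 1 point per fish. Circles are controls, squares R-venlafaxine and triangles S-venlafaxine, and the 3 groups overlap.

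R-venlafaxine was compared with control to ask which liver genes respond to that enantiomer. No gene passed in edgeR's quasi-likelihood test, where 0 of 59733 genes were called and the lowest adjusted p was 1. At an unadjusted p under 0.05 there were 1933 genes, 882 higher and 1051 lower, fewer than the 2987 that evenly spread p-values would give. The gene with the lowest p among those lower after R-venlafaxine was TRINITY_DN185_c20_g1, at 4.87 ± 1.42 TPM in controls and 1.65 ± 0.47 TPM in R-venlafaxine fish (SD, n = 6 each). Its log2 fold change was -1.57 (SE 0.3, edgeR adjusted p = 1), and its values in all 6 exposed fish lay below all 6 controls. The gene with the lowest p in the other direction, TRINITY_DN3611_c6_g1, was listed at 0 in all 6 controls and averaged 2.37 ± 1.69 TPM in R-venlafaxine fish, with 1 of those 6 also at 0 (edgeR adjusted p = 1). Neither pattern was particular to R-venlafaxine. In S-venlafaxine fish TRINITY_DN185_c20_g1 averaged 2.15 ± 1.01 TPM and TRINITY_DN3611_c6_g1 2.56 ± 2.1 TPM, the latter with 1 of 6 at 0 (SD, n = 6 each). DESeq2 called 70 genes in the same comparison, 19 higher and 51 lower, both of these genes among them. In 36 of the 70, 1 of the 2 groups was listed at 0 in all 6 libraries.

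S-venlafaxine was compared with control in the same fit. The main edgeR test called a single gene lower and none higher. TRINITY_DN2810_c5_g1 fell from 0.757 ± 0.524 TPM in controls (SD, n = 6), where the fish ranged from 0.25 to 1.58 TPM, to a listed value of 0 in all 6 S-venlafaxine fish (edgeR adjusted p = 0.0203). At an unadjusted p under 0.05 there were 1927 genes, 905 higher and 1022 lower. TRINITY_DN16936_c2_g2 had the lowest p among the more abundant genes that were lower, at 8.34 ± 4.27 TPM in controls and 1.77 ± 0.113 TPM in S-venlafaxine fish (SD, n = 6 each), a log2 fold change of -2.25 (SE 0.365) that did not pass (edgeR adjusted p = 0.331). Its S-venlafaxine values lay within 1.65 and 1.92 TPM, while controls spanned 1.8 to 13.33 TPM. TRINITY_DN1583_c0_g1 had the lowest p among those higher, at 2.69 ± 0.567 TPM in controls and 5.75 ± 1.99 TPM after S-venlafaxine, a log2 fold change of 1.06 (SE 0.202, edgeR adjusted p = 1). The call of TRINITY_DN2810_c5_g1 ended in 8 of the 13 alternative settings that tested it and on leaving out any of 11 of the 18 libraries, namely control 5, R-venlafaxine 3 to 6 and all 6 S-venlafaxine fish. In those 11 fits its edgeR adjusted p was 0.0501 to 0.0697, close to the threshold. They tested 64222 to 64836 genes, against 59733 in the main fit. The loss therefore does not show that those fish carried the call. DESeq2 called 65 genes, 29 higher and 36 lower, all 3 of these genes among them, and in 36 of the 65 1 group was listed at 0 throughout.

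**Figure D2:**
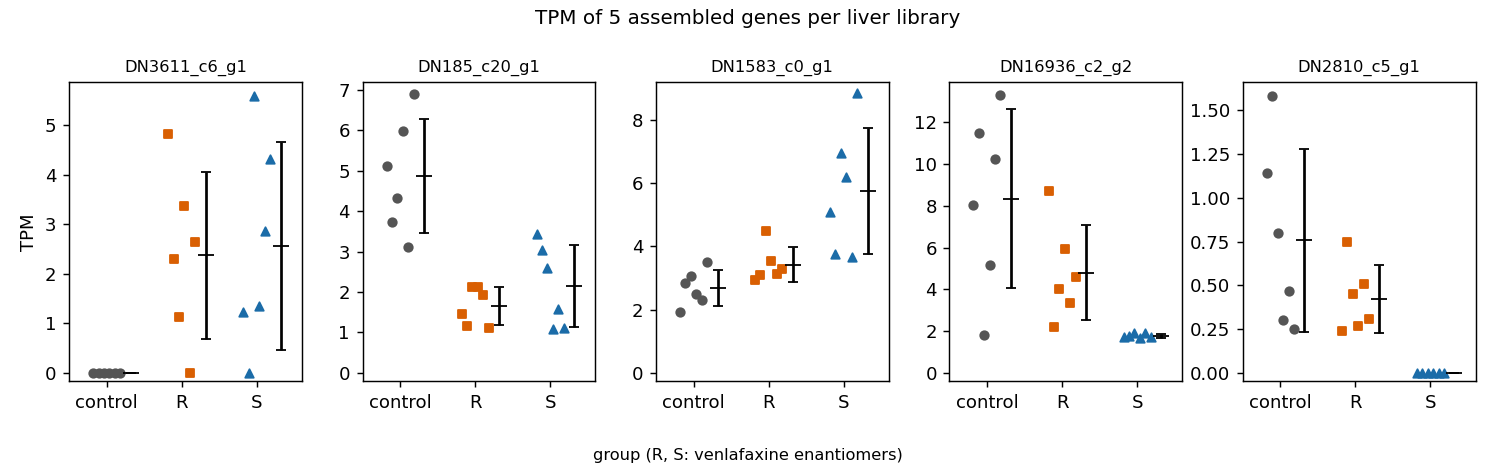
TPM (vertical, linear) of 5 assembled genes in each liver library of the control, R-venlafaxine and S-venlafaxine groups, 6 fish per group, with the mean and SD of each group in black beside the points. TRINITY_DN2810_c5_g1 is at 0 in all 6 S-venlafaxine fish and TRINITY_DN3611_c6_g1 at 0 in all 6 controls, and only the first was called by edgeR.

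The enantiomers were compared directly, at the same nominal dose and time, because they differ only in the handedness of the molecule. The one gene called was again TRINITY_DN2810_c5_g1, at 0.422 ± 0.192 TPM (SD, n = 6) in R-venlafaxine fish and listed at 0 in all S-venlafaxine fish (edgeR adjusted p = 0.0483). The main edgeR test called no gene higher after S-venlafaxine than after R-venlafaxine, and 2060 genes had an unadjusted p under 0.05. This call ended in 10 of those 13 settings and on leaving out any single library other than control 6. Leaving out 1 of those libraries gave an edgeR adjusted p of 0.0516 to 0.168. A joint test of all 3 groups called 0 genes in edgeR, with a lowest adjusted p of 0.0851 and 2040 genes at an unadjusted p under 0.05. DESeq2 called 74 genes between the enantiomers, 41 higher and 33 lower after S-venlafaxine, and 43 in its joint test. TRINITY_DN16936_c2_g2 had a log2 difference of -1.43 (SE 0.356) between S- and R-venlafaxine, with a 95% interval of -2.18 to -0.68 and an edgeR adjusted p of 1. For TRINITY_DN185_c20_g1 that interval ran from -0.27 to 0.98, so a difference of up to 0.98 in log2 between the enantiomers was not excluded.

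What size of change these groups could show was measured in several ways. For the 27869 genes with a mean log2 CPM of at least 0, the median SE of a log2 fold change was 0.252. The 95% interval lay within 2-fold in either direction for 63.7% of these genes in R-venlafaxine against control, 63.8% in S-venlafaxine against control and 64.0% between the enantiomers. It lay within 4-fold for 84.5%, 84.1% and 84.2%. Changes were also implanted in 200 real genes drawn from the same 27869 genes. Recovery among the less abundant tested genes, TRINITY_DN2810_c5_g1 included, was therefore not measured. In each draw all 200 genes were changed at once, and the simulated counts also held 200 changed genes. That many changes let larger p-values pass the adjustment. A change confined to a few genes would be called less often, and its recovery was not measured. For R-venlafaxine against control, 35.5% of 2-fold, 67.7% of 4-fold, 78.2% of 8-fold and 83.3% of 16-fold changes were called. For S-venlafaxine against control the shares were 35.7%, 68.2%, 79.3% and 84.8%. In fully simulated counts, with 50 genes per fold size, 20% and 24% of 2-fold changes were called for R- and S-venlafaxine against control. Those shares were lower than the implanted ones, a difference that was not tested. Between the enantiomers, where no changes were implanted in real genes, the simulated share was 28%. The shares at 4-fold were 84%, 84% and 78%.

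**Figure D3:**
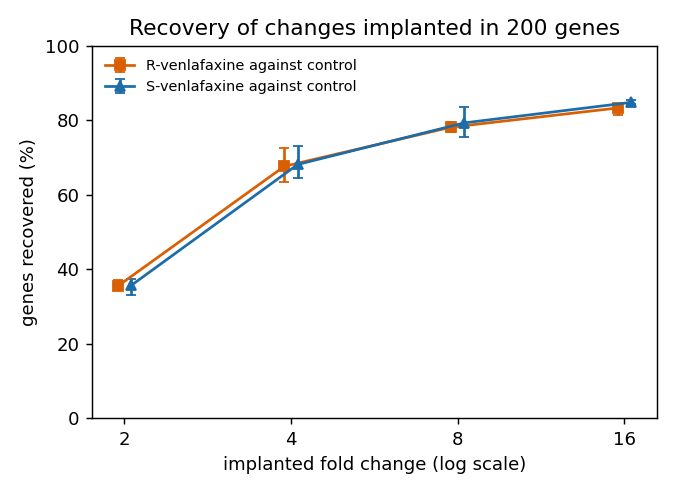
Percent of 200 implanted genes called by edgeR (vertical) against the implanted fold change (horizontal, log scale), with points at the mean of 3 draws and bars from the lowest to the highest draw. The genes were drawn from those with a mean log2 CPM of at least 0, and all 200 were changed at once. Recovery rose from 35.5% at 2-fold to 83.3% at 16-fold for R-venlafaxine against control.

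Whether both enantiomers moved the same genes was examined across the 59733 genes, which are not independent replicates. Fold changes of the 2 exposures correlated at r = 0.510, but both were measured against the same controls. Simulating all 18 libraries, controls included, with independent genes and no difference between groups gave a mean r of 0.502. Reassigning the libraries at random gave a mean of 0.498, within 0.438 and 0.541. The covariance was 0.309, against 0.273 in the simulation and 0.293 on reassignment, and 38 of 200 reassignments were as large. With the controls split 3 and 3, the mean r was 0.025 and 50.0% of genes had the same sign. As edgeR called 0 genes after R-venlafaxine, no overlap of its calls could be formed, and the overlap of DESeq2's calls was not computed.

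No difference in the spread between fish was detected for either exposure. The mean distance of a library to its group's mean in log2 CPM was 321.2 ± 11.2 in controls, 324.2 ± 5.49 after R-venlafaxine and 328 ± 8.76 after S-venlafaxine (SD, n = 6 each). Two-sided exact permutation gave p = 0.567 for R-venlafaxine against control, 0.281 for S-venlafaxine against control and 0.383 between the enantiomers. Among 18 tests of depth and composition, 1 passed. S-venlafaxine libraries were shallower than R-venlafaxine libraries, at a mean of 50.0 against 55.9 M estimated counts (exact permutation p = 0.002165, adjusted p = 0.039). The totals did not overlap, with S-venlafaxine at most 51.5 M and R-venlafaxine at least 51.7 M. Leaving out any 1 of the 6 S-venlafaxine libraries raised the adjusted p above the threshold (exact permutation, adjusted p = 0.1169 to 0.2727). The difference then still lay between -6.14 and -5.32 M, so this rise does not show that 1 fish carried it. S-venlafaxine fish also had more genes that reached 1 TPM in that fish and were found in no other, 1677 ± 341 against 1121 ± 274 in controls (SD, n = 6 each), a difference that did not pass adjustment (exact permutation p = 0.0195, adjusted p = 0.175). R-venlafaxine fish had 1678 ± 840 such genes (SD, n = 6), which did not pass against control either (exact permutation p = 0.1515, adjusted p = 0.6).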

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

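The tests of zeros, of rounding and of DESeq2's all-or-none genes were chosen only after the results were seen, while the counts over other splits of the libraries were planned. TRINITY_DN2810_c5_g1 stood out because its level differed between the enantiomers, with an edgeR adjusted p of 0.0483 for S- against R-venlafaxine. The lowest value among the 12 control and R-venlafaxine fish was 0.24 TPM and the table's step is 0.01, but the low-count filter, at about 0.192 TPM, keeps most lower genes out of the test, so a level near the floor stays open. A set of fish that lack the gene by chance stays open too. For any 6 libraries, the genes at 0 in all of them and above 0 in at least 10 of the other 12 were counted, and 75.24% of all 18564 sets of 6 held at least the 2 genes seen for S-venlafaxine. The 18 libraries were also regrouped at random into 100 splits, with the real grouping counted among them. As many genes as in S-venlafaxine against control were called in 6 of 100, and as many as between the enantiomers in 10 of 100. Each had a real count of 1 and a highest other count of 1, so chance was not excluded. An effect of S-venlafaxine on this gene also stays open and was not tested in other fish.

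For R-venlafaxine against control and for the joint test, edgeR's real count was 0. All 100 of 100 splits reached it, which was certain because no count is lower, so the splits decide nothing there. The highest other count was 1. At an unadjusted p under 0.05, random splits gave medians of 1995 genes for R-venlafaxine against control, 1967 for S-venlafaxine against control and 2074 between the enantiomers, beside real counts of 1933, 1927 and 2060. Evenly spread p-values would give 2987 genes, above those medians and the real counts, while the highest random splits reached 4352, 3797 and 4157. DESeq2's larger counts in the 3 comparisons of pairs of groups were not unusual for these libraries either, while its joint count of 43 was not set beside random splits. As many genes as its 70 for R-venlafaxine against control came from 41 of 80 splits, the real one again included, with a highest other count of 614. Its 65 for S-venlafaxine against control were reached by 53 of 80 splits (highest other 442), and its 74 between the enantiomers by 30 of 80 (highest other 394). Chance was not excluded for any of the 3. Some random groups had several times the real count, and the cause was not tested. Of the 209 calls, 55.98% had a whole group at 0, against 0.6% of the genes tested. Any test favours genes at 0 in 1 group and well above 0 in the other, whatever the reason for the zeros. The share was not taken in the random splits. It therefore does not show whether genes that some fish have and others lack supply such calls.

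Libraries far from the rest of their group were looked for in 48 sets of 6 values, and 6 were marked. Among the 21 sets that are measures of whole libraries, chance would mark about 1 in 20 and 1 was marked. That rate does not hold for the 12 sums of gene blocks and the 15 sets of named genes, which were picked for how they vary. In S-venlafaxine 4 the 10 most abundant genes held 17.67% of the library, with the next fish of that group at 15.87%. The other 5 concern blocks of genes that rise and fall together between fish. The first block summed to 6389 TPM in R-venlafaxine 5, with the next fish of its group at 1683 TPM, and to 778.7 TPM in control 5, with the next control at 240.04 TPM. The second block summed to 24.16 TPM in control 1, to 50.01 TPM in R-venlafaxine 6 and to 225.9 TPM in S-venlafaxine 2, with the next fish of each group at 0.72, 10.43 and 45.81 TPM.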

How the results depend on the processing

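Alternatives were fixed before the data were examined, except 4 chosen after seeing them: leaving out R-venlafaxine 5 and S-venlafaxine 4 together, summing counts per assembly component, a filter at a mean of 1 TPM, and all exposed fish against controls, which is given under the other observations. DESeq2 raised every count, from 0 to 70 for R-venlafaxine against control, from 1 to 65 for S-venlafaxine against control, from 1 to 74 between the enantiomers and from 0 to 43 in the joint test. Among the other settings, R-venlafaxine against control and the joint test kept a count of 0. For S-venlafaxine against control the count went from 1 to 0 with no filter, the CPM filter, only the groups compared, limma voom, either log2 TPM scale, leaving out both of those libraries and the mean TPM filter, besides the replicate block. Between the enantiomers it went to 0 in those settings and also with upper-quartile scaling (adjusted p = 0.0504) and the library letter as a block. The single gene was not tested under the CPM and mean TPM filters, which explains its loss there. The cause was not tested for the others. Over the alternatives its adjusted p ran from 3.61e-11 to 0.864 for S-venlafaxine against control and from 1.93e-08 to 1 between the enantiomers. With 2 libraries per letter summed, S-venlafaxine against control still had 1 call, but not this gene (adjusted p = 0.604).

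With the replicate number as a block, the count was 0 in all 3 comparisons and the joint test. Same-numbered libraries of different groups correlated at -0.08 to 0.156, with a mean of 0.014 over 18 pairs, so the numbers were not taken to pair the fish. As a hint from the data towards pairing, 7 of 18 libraries correlated best with a library of their own number, where chance would give about 3. Within a group, these deviations correlated at a mean of -0.207 for the same letter in the names (9 pairs) and -0.198 for different letters (36 pairs). Subtracting the mean of 6 libraries forces such values below 0, so only the gap between the 2 kinds of pair can be read.

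Leaving out 1 library at a time gave 0 to 2 genes for R-venlafaxine against control, 0 to 2 for S-venlafaxine against control, 0 to 1 between the enantiomers and 0 to 1 in the joint test. R-venlafaxine against control reached 2 without control 1 and 1 without control 5 or R-venlafaxine 2. S-venlafaxine against control reached 2 without control 1 or control 3, and without control 3 the second was TRINITY_DN16936_c2_g2 (edgeR adjusted p = 0.00658). It was 0 without control 5, R-venlafaxine 3, 4, 5 or 6, or any S-venlafaxine library. The count between the enantiomers was 0 without those R- and S-venlafaxine libraries, R-venlafaxine 1 or control 2, 3 or 4, and the joint test reached 1 without control 3, control 5 or R-venlafaxine 2. The covariance of the fold changes of both exposures, 0.309, moved to 0.461 with DESeq2, 0.236 with the CPM filter and 0.0219 with split controls, where the shared controls are removed by construction, and to 0.299 to 0.384 on leaving out 1 library. The deficit in depth of S- against R-venlafaxine libraries ranged from -6.69 to -4.54 M estimated counts and no longer passed without any 1 of the 6 S-venlafaxine libraries. Differences that had not passed changed sign on leaving out 1 library for depth of R-venlafaxine against control (-0.925 to 3.43 M estimated counts), its share in the top 100 genes (-0.88 to 0.417 percentage points) and its distance to the group mean (-1.27 to 5.58). The same held between the enantiomers for genes above 0 (-4042 to 1432), genes at 1 TPM (-80.1 to 1398) and genes found in 1 fish alone (-152 to 295).

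The share of variance between groups was 12.48% to 12.99% on leaving out 1 library, and no alternative passed. Top-gene shares from the TPM table were equal by construction. The alternatives for the fixed gene lists were not run because no identifier carried a symbol. What depth limits cannot be said from these tables, as the deposited values are rescaled TPM and do not show how many reads stand behind a value.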

Other observations

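The tests in this part were chosen only after the result was seen. Among 18752 assembled genes that varied strongly between fish, 4 blocks of at least 40 genes followed a common pattern over the 18 libraries. The first held 1007 genes, and its sum ranged from 1.84 TPM in control 3 to 6389 TPM in R-venlafaxine 5. Controls 1, 2 and 3 lay between 1.84 and 3.69 TPM and S-venlafaxine 1 at 5.97 TPM, while R-venlafaxine 1 and S-venlafaxine 3 reached 1683 and 2000 TPM. The second block held 67 genes and peaked at 225.9 TPM in S-venlafaxine 2. The third held 47 genes and was abundant, at 51.15 to 4458 TPM, with controls 1, 5 and 6 between 51.15 and 59.1 TPM, controls 2, 3 and 4 between 840 and 3292 TPM, and the exposed fish between 385 and 4458 TPM. The fourth held 44 genes at 97.2 to 1618 TPM.

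No block passed a test of differences between groups. The third block averaged 2.31 higher on the log2 scale after S-venlafaxine than in controls (exact permutation p = 0.1104) and 2.02 higher after R-venlafaxine (exact permutation p = 0.1558), both with an adjusted p of 0.4156 over 12 tests. The spread of its log2 sum was 2.85 in controls, 1.5 after R-venlafaxine and 1.13 after S-venlafaxine (SD, n = 6 each), and the difference in spread was not tested. The labels do not give the sex of the fish, so a difference between the sexes was not tested for any block.

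For the first block, depth of the library is argued against, since its highest sum was 3472.3 times the lowest while library totals spanned 1.5-fold. Independent variation of single genes is argued against as well, since permuting each gene's values over the libraries 5 times gave sets of at most 7 genes, against 811 around the first gene. RNA of another source, such as another organism or tissue carried with the liver, could give such a block, because its genes would then keep 1 ratio to each other. A slope against the block's sum, both in log2, could be taken for 422 of the 1007 genes in the 11 libraries with most of the block, and its median was 1.025 with the middle 90% within 0.833 and 1.25. That leaves the source open, since most of the genes are not covered, members were picked for following 1 pattern, and the second block's slopes, 0.779 to 1.22, were similar. A shared response of the fish's own genes could give such slopes too. An effect of venlafaxine cannot be told apart from variation between fish, as the lowest exact permutation p against control was 0.1039 with 6 fish per group and an SD of the log2 sum of 3.6 in controls and 3.04 in R-venlafaxine fish.

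The amount of the first block moved with the number of genes seen in 1 fish alone. Over the 18 libraries, the log2 sum of the block and the count of such genes correlated at Pearson r = 0.779 (permutation p = 0.0001) and Spearman rho = 0.765 (permutation p = 0.0002), and r was 0.805 without the 2 libraries farthest from the median of the block. Only 540 of the block's 1007 genes were tested by edgeR, and none was called, with a lowest edgeR adjusted p of 1 in each comparison. Their median log2 difference was 2.80 for R-venlafaxine against control, 1.47 for S-venlafaxine against control and -1.33 between the enantiomers, with 54, 3 and 0 genes at an unadjusted p under 0.05.

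Of the 59733 genes tested, 39.8% were listed at 0 in at least 1 library, low genes included, while 518 were at 5 TPM or more in at least 3 fish and at 0 in at least 3 others. Among 1547 genes averaging 50 TPM or more, the median SD between fish of a group was 0.307 on the log2(TPM + 1) scale, yet 44 had a highest fish over 100 times the lowest. Taking all 12 exposed fish together against the 6 controls, an alternative added after seeing the data, edgeR called 0 genes, with 1980 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0823.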
